A study of Drosophila melanogaster with 3 samples.

How the data were processed

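The data were chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole Drosophila melanogaster prepupae that carried a transgene for the protein CG8119 fused to enhanced green fluorescent protein. An antibody against the fluorescent tag pulled down the fusion protein with the chromatin around it, and the chromatin had been sheared by sonication, per the labels. The 3 samples are biological replicates 1, 2 and 3 of 1 group, as numbered in the labels. No second group was analysed here, so no comparison between conditions was made, and values were compared between replicates, between genomic features and with chance. Because a tagged transgene was used, binding here means that sequenced fragments were concentrated at a place by the pull-down, and it does not show that a neighbouring gene is regulated.

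Each replicate has a ranked peak list and a shorter thresholded peak list, and the whole series has further thresholded lists, all on genome build dm6 per the deposited README texts. The lists are named for the irreproducible discovery rate (IDR), an estimate of the chance that a peak is not repeated between a pair of ranked peak sets. The aligner, the peak caller and their versions are not given in the sources used here, and neither is which reads were paired for the IDR within a replicate. In every deposited list a scaled IDR score is given per peak, and its smallest value in the thresholded lists of the replicates was 830, which matches an IDR of 0.01. The deposited ranked lists also hold the −log10 of the global IDR for each peak. The deposited signal of a peak is the authors' own value, on a scale that the sources used here do not state, and it was used to rank peaks within a list and to describe peaks. Where a mean and SD of the signal over replicates is given, the SD can also hold differences of scale between the lists. No read counts were at hand, so the depth of each replicate is unknown, and the length of the peak list is the only trace of it. Of the ranked peaks with an IDR of 0.01 or less, 145 in replicate 1, 136 in replicate 2 and 89 in replicate 3 had no entry in the thresholded list. They enter only the alternative that takes the ranked lists at the same IDR.

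Summit positions of the thresholded lists on 2L, 2R, 3L, 3R, 4, X and Y were joined into loci wherever neighbouring summits lay within 150 bp. A locus with a summit of all 3 replicates is called a shared locus, and its centre is the median of its summits. The strength of a locus is the mean, over the 3 replicates, of the percentile of its signal within the replicate's list. Gene models came from Ensembl release 115 of the same build, without transposable elements. A summit within 500 bp of any annotated transcript start was counted as promoter, and the remaining summits went, in this order, to 5′ UTR, 3′ UTR, coding exon, other exon, intron or intergenic DNA. A gene was called bound if a shared locus lay within 500 bp of an annotated start of it. Where a locus lies between divergent starts, both genes count.

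Chance levels came from 1000 circular shifts of the summits along each chromosome arm. The shifts also place summits in repeats and in DNA where reads map poorly, so they set a chance level for position along the arm and not for mappable DNA. Gene lists, 31 in number, were tested with Fisher's exact test, two-sided, members against all other protein-coding genes (for tRNA genes, all other genes), with 0.5 added to each count for the odds ratio and Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Of the listed symbols, 6 had no match, and 38 older symbols were matched through synonyms. Fixed sequence words, 30 in number, were sought on both strands within 100 bp of each locus centre and in a window of the same width 500 bp to a randomly drawn side, and were compared with the exact McNemar test. The same words were compared at promoter loci with unbound protein-coding starts at the same offset and the same GC content in steps of 5 percentage points. Every 7-base word was ranked on 2L and 2R, and the 20 leading words were tested on 3L, 3R and X. Loci, genes and words are not independent replicates, and p-values over them describe these lists. Coordinates are 1-based.

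Named genes follow a rule: the tagged gene, the genes nearest the 25 strongest shared loci, up to 4 bound members of each list by strength, up to 4 members without a shared locus in alphabetical order for lists past the threshold, and the 5 genes whose bodies hold the most shared loci. The tests, lists, words and this rule, and most of the alternatives, were fixed before the data were examined. The random draw of the flank sides was not: a first draw was replaced by the reported one after a run on the real lists had been seen, which changed the 7-base words carried forward and the number of fixed words that passed. The alternatives left out each replicate in turn, changed the join distance, the overlap rule, the peak threshold, the number of replicates required and the promoter and motif windows, and replaced Fisher's test by circular shifts. Another alternative of the list test counted a gene as bound by a shared locus anywhere in its body or within 500 bp of it. Longer genes have more room to count there, so it does not test binding at starts. The ranked lists at the same IDR, the first and further draws of the flank side, the arm test without each replicate and lists without genes caught by a name prefix were added after the data were seen. The procedure was tested on simulated data, after it had first been run on the real lists: from 3036 simulated positions it recovered 100% of the loci kept in all 3 simulated replicates, called a planted list and none of 200 random lists, and carried a planted 7-base word forward, while 1 of 100 random words passed the motif test. The simulated summit and flank windows had the same base composition, unlike the real ones (33.6% GC at summits, 42.8% in flanks). The count of random words therefore does not tell how often words pass through composition alone. The simulated bound genes and random lists were drawn evenly from protein-coding genes, whatever their length, number of starts or neighbours. The count of random lists therefore does not tell how often real lists pass through such features. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.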

Results

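CG8119 is an uncharacterised protein-coding gene on the X chromosome of Drosophila melanogaster (identifier FBgn0030664, X, 15662585 to 15663319, plus strand, build dm6). The series measured where the protein, tagged with enhanced green fluorescent protein, lies along the genome of whole prepupae aged 1 day, the stage at which larval tissues begin to give way to adult ones under the hormone ecdysone. There were 3 biological replicates of 1 group. The thresholded lists held 7279 peaks in replicate 1, 6769 in replicate 2 and 4608 in replicate 3, or 6219 ± 1418 (SD, n = 3). The longest list was 1.58 times the shortest. The median peak width was 375 bp ± 15 (SD, n = 3), and the median signal, in the authors' units, was 95.5 ± 1.49 (SD, n = 3). Read depth is unknown for all 3 replicates.

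The replicates had many sites in common. Their summits formed 9014 loci, of which 3746 (41.6%) held a summit of every replicate, 1919 of exactly 2 and 3349 of 1. Circularly shifted summits gave 1.71 such shared loci on average and at most 8 in 1000 draws (one-sided permutation p = 0.001, the smallest that the draws can give). Shared loci made up 82% of the loci of replicate 3, 56.1% of those of replicate 2 and 52.2% of those of replicate 1. Loci found in 1 replicate were weak there: their median signal percentile was 18.3 in replicate 1, 15.4 in replicate 2 and 10.4 in replicate 3. Across the shared loci, the signal ranked alike in each pair of replicates, with Spearman's rho of 0.880 for replicates 1 and 2, 0.874 for 1 and 3 and 0.879 for 2 and 3, and Pearson's r of log2 signal of 0.908, 0.911 and 0.913. The permutation p was 1e-05 for each of the 3 pairs, the smallest that 100000 permutations can give, and 1e-05 after Benjamini-Hochberg adjustment. These correlations are across loci, which are not independent replicates.

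The strongest shared locus of all 3 replicates lay in an intron of CG11050 (2L, 6612362 to 6613021), with a signal of 1705 ± 347 (SD, n = 3). The next was intergenic, 11923 bp from the nearest annotated start, that of CG13323 (2R, 13035083 to 13035544, signal 1273 ± 157). The third lay in an intron of Trl, which encodes the GAGA factor, a DNA-binding protein of chromatin (3L, 14759321 to 14759718, 1198 ± 118). Among the 25 strongest loci, promoter sites included Ugalt, a UDP-galactose transporter (offset of −39 bp from the start), PNPase, a polynucleotide phosphorylase of mitochondria (83 bp), Fkbp14 (−126 bp), CenG1A (−103 bp), gish, a casein kinase (−159 bp), the glycolytic gene Gapdh2 (−155 bp) and Btk, a tyrosine kinase (−152 bp). CG18549, CG31145, CG14100, CG1635 and the noncoding genes lncRNA:CR31044 and lncRNA:CR44339 also had promoter sites. Chro, which encodes a chromodomain protein of interbands (3L, 22878741 to 22879065), and ph-p, a Polycomb group gene (X, 2136930 to 2137547), closed the list at signals of 808 ± 95.3 and 815 ± 99.4 (SD, n = 3). The other loci of this group were nearest to CG31668, lncRNA:CR44619, HmgZ, CG12769, CG4496, lncRNA:CR46035 and CG32772. The site nearest HmgZ, which encodes a high mobility group protein of chromatin, lay at an offset of −603 bp from the nearest start, in an intron shared with HmgD. The mean signal percentile of the 25 loci was at least 99.6.

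Promoters and introns held most of the summits, and coding exons held almost none. Promoters took 33.7% ± 2.07 of the summits (SD, n = 3) against 13.5% after circular shifts, a ratio of 2.5. Introns took 47.4% ± 1.48 (SD, n = 3) against 39.4%. Coding exons took 0.143% ± 0.0859 (SD, n = 3) against 13%, 3′ UTRs 0.697% ± 0.0520 against 5.06%, and intergenic DNA 16.3% ± 0.599 against 27.4%. For these 5 classes the two-sided permutation p was 0.002 in each replicate, the smallest that 1000 draws can give, and each difference was larger than the SD between replicates. For 5′ UTRs (0.671% against 0.781%) and other exons (0.956% against 0.815%) the permutation p reached 0.837 and 0.787. Of the 1198 shared loci at promoters, 933 (77.9%) had their centre upstream of the nearest start, with a median offset of −153 bp and quartiles of −248 and −39 bp. Promoter loci were stronger than the rest, with a median signal percentile of 73.4 against 64.4 for intronic and 62.1 for intergenic shared loci, a difference that was not tested.

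**Figure D1:**
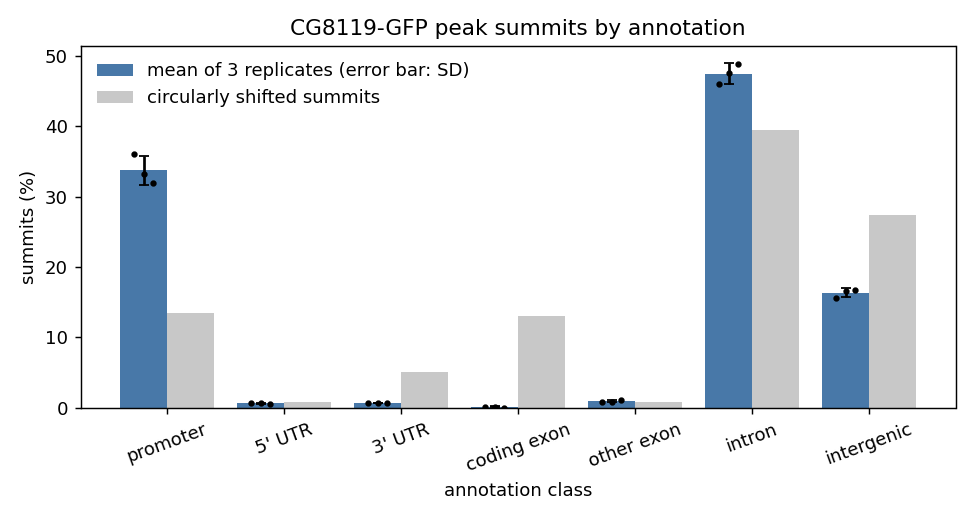
Share of peak summits (%) in each annotation class, as the mean of the 3 replicates (bars, with SD) with each replicate as a point, beside the mean after circular shifts (grey bars). Promoters stand at 33.7% against 13.5%, and coding exons at 0.143% against 13%.

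The shared loci were spread unevenly over the chromosome arms. The X held 770 of them, 20.6%, against 15.7% of the protein-coding genes (odds ratio 1.39, Fisher's exact test, two-sided, adjusted p = 4.0e-11), and the X share of all peaks was 19.8% ± 0.533 (SD, n = 3). The X makes up 17.1% of the length of these arms. 3L was also above its share of genes, with 23% against 19.6% (exact test, adjusted p = 8.4e-06). In the same exact test, 2R, with 16.9% against 20.4% (adjusted p = 3.4e-06), 3R, with 22.1% against 24.5% (adjusted p = 0.0033), and 2L, with 17.4% against 19% (adjusted p = 0.021), were below theirs. Of the length of the arms examined, 2L makes up 17.1%, 2R 18.4%, 3L 20.4% and 3R 23.3%, so that by length 2L was not below its share, and the shares of length were not tested. Chromosome 4 held 1 shared locus, against 80 protein-coding genes (exact test, adjusted p = 5.4e-07), and the Y held none, against 23 genes (adjusted p = 0.0095). Sex was not given for the samples, and a mixture of sexes would carry fewer copies of the X than of the autosomes.

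Of 13968 protein-coding genes, 1266 (9.06%) had a shared locus within 500 bp of a start, and so had 152 of 2808 noncoding RNA genes (5.41%), 12 of 290 tRNA genes and 3 of 330 pseudogenes. No snRNA, snoRNA or rRNA gene did. Of the 31 gene lists, 6 held more bound genes than the remaining protein-coding genes, 4 held fewer than their comparison genes, and 21 did not pass the threshold. At an unadjusted p under 0.05 there were 12 lists. A gene counts as bound through any of its annotated starts, and the exact test does not allow for their number. After circular shifts, the ecdysone list had 2.19 of 39 genes bound, circadian 0.876 of 14 and Polycomb and Trithorax 1.955 of 45. The EGFR list had 1.15 of 27, insulator 1.07 of 29 and Notch 1.07 of 33. For all protein-coding genes the share was 3.32%. Where a list exceeds that share, its odds ratio can partly reflect this.

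Genes of the ecdysone response and nuclear receptors were bound more often than other genes: 12 of 39 (30.8%) against 9.0% of the rest (odds ratio 4.59, Fisher's exact test, adjusted p = 0.0017). The strongest were E23, an ecdysone-induced ABC transporter, at a mean signal percentile of 98.3 ± 1.30 (SD, n = 3), Ldh, the lactate dehydrogenase gene, at 97.2 ± 1.45, Eip75B, a nuclear receptor, at 94.8 ± 1.91, and Eip93F, a transcription factor of the late ecdysone response, at 87.3 ± 5.37. Blimp-1, br, crol and dsf, from the same list, had no shared locus at a start. With summits joined within 50 bp, the call for this list was lost (exact test, adjusted p = 0.086, the highest of 12 alternatives of this test). The lowest was 5.4e-09, with loci anywhere in the gene body counted. Among the alternatives at starts the lowest was 2.4e-05 (exact test), without replicate 3.

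Signalling genes were bound in the Notch and EGFR lists. In the Notch list 9 of 33 genes (27.3%) were bound (odds ratio 3.91, Fisher's exact test, adjusted p = 0.012), led by numb, an inhibitor of Notch, at 96.7 ± 0.769, gro, a corepressor, at 94.2 ± 1.39, E(spl)m7-HLH, a repressor induced by Notch, at 81.8 ± 8.56, and aph-1, a part of the gamma-secretase, at 81.7 ± 3.55 (percentiles, SD, n = 3). BobA, Brd, Delta and dx were not bound. This result ended when the promoter window was narrowed to 200 bp (odds ratio 0.866, exact test, adjusted p = 1). Over the other alternatives and this one, the adjusted p ran from 0.00068, with loci anywhere in the gene body counted, to 1. In the EGFR and Ras list 8 of 27 genes (29.6%) were bound (odds ratio 4.39, exact test, adjusted p = 0.012), among them Mkp3, a phosphatase of the pathway, at 95.3 ± 0.843, the ligand gene spi at 94.4 ± 2.49, the gene of the secreted inhibitor aos at 90.4 ± 2.28, and edl, an antagonist of an Ets factor, at 75.5 ± 9.02. cic, cnk, Dsor1 and ed were not bound. The EGFR call was lost in 4 of 12 alternatives of the exact test, with adjusted p from 3.1e-09 to 0.40 over the 12. This lowest value also came with loci anywhere in the gene body counted.

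Genes for chromatin proteins formed another group. Of the insulator and architectural list 8 of 29 (27.6%) were bound (odds ratio 3.98, Fisher's exact test, adjusted p = 0.015), led by Chro at 99.6 ± 0.0950, Cp190, an insulator cofactor, at 96.0 ± 2.46, hng3 at 94.7 ± 1.13, and Trl at 90.6 ± 1.43 (percentiles, SD, n = 3). Adf1, Cap-H2, Clamp and CTCF were not bound. Of the Polycomb and Trithorax list 10 of 45 (22.2%) were bound (odds ratio 2.98, exact test, adjusted p = 0.021), led by ph-p at 99.6 ± 0.0966, brm, the ATPase of a chromatin remodeller, at 96.5 ± 1.08, jing at 93.9 ± 2.28, and Trl, which belongs to both lists. ash1, ash2, Asx and Bap111 were not bound. The Polycomb and Trithorax list no longer passed without replicate 3 (exact test, adjusted p = 0.073) or with a promoter window of 1000 bp (adjusted p = 0.053). The range was 0.0023 to 0.073 over 12 alternatives of the exact test, the lowest with loci anywhere in the gene body counted. The shared locus of brm lies closer to the start of Arl1, and that of Cp190 closer to CG4338. Of 90 bound list members named here, 17 had their locus closer to the start of another gene. In the circadian list 5 of 14 genes (35.7%) were bound (odds ratio 5.83, exact test, adjusted p = 0.021), led by sgg, a kinase shared with the Wnt pathway, at 95.3 ± 2.26, cry, a blue-light receptor, at 82.7 ± 3.50, and the bZIP factor genes Pdp1 at 56.5 ± 12.9 and vri at 46.2 ± 16.4. CkIIalpha, Clk, cwo and cyc were not bound. The circadian list lost its call in 6 of 12 alternatives of the exact test, with adjusted p from 0.019 to 0.44 over the 12.

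The chemosensory receptor, cuticle protein, histone and tRNA lists held fewer bound genes than their comparison genes. None of 179 chemosensory receptor genes was bound, Gr10a, Gr10b, Gr21a and Gr22a among them, which allows a share of up to 1.68% (odds ratio 0.0275, Fisher's exact test, adjusted p = 1.7e-06). Of the cuticle protein list 3 of 138 (2.17%) were bound (exact test, adjusted p = 0.012), namely Cpr50Ca, Cpr72Eb and Cpr, and the last was caught by its symbol alone, since it encodes a cytochrome P450 reductase. Acp1, Acp65Aa, Ccp84Aa and Ccp84Ab were not bound. In the histone list 1 of 115 genes was bound (exact test, adjusted p = 0.0046), His3.3B, which encodes a replacement histone. His1:CG31617, His1:CG33801, His1:CG33804 and His1:CG33807 were not bound, and without His3.3A, His3.3B and His4r none of the 112 members left was bound. Histone genes lie in near-identical copies, so peaks there are uncertain. Of the tRNA genes 12 of 290 (4.14%) were bound against 8.12% of all other genes (exact test, adjusted p = 0.037), with tRNA:Tyr-GTA-1-8 the strongest at 96.9 ± 0.859 (SD, n = 3), followed by tRNA:Gln-TTG-2-1, tRNA:Phe-GAA-1-6 and tRNA:Ala-AGC-2-2. tRNA:Ala-AGC-1-1, tRNA:Ala-AGC-2-1, tRNA:Ala-AGC-2-10 and tRNA:Ala-AGC-2-11 were not bound, and these multicopy genes are likewise uncertain. Among 12 alternatives that set a list against other genes by the exact test, the histone list passed in 12 (adjusted p from 9.9e-07 to 0.028) and the cuticle list in 11 (3.6e-05 to 0.068, the highest in the stronger 50% of each peak list). All 12 count each near-identical histone copy as a separate gene, so passing in all of them does not lift the uncertainty there. The tRNA list passed in 6 of these 12 (exact test, adjusted p from 7.4e-07 to 0.12) and was lost, among others, without replicate 3 (adjusted p = 0.12). The lowest values of the histone and tRNA lists came with loci anywhere in the gene body counted, where gene length also plays a part. Against random positions, by circular shifts, which is another question, the cuticle, histone and tRNA lists did not pass (permutation test, adjusted p = 0.94, 0.86 and 0.46).

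The remaining 21 lists did not pass against other genes. In 12 alternatives of the exact test, 5 of them passed at least once: Hippo, JAK-STAT and growth control in 4 (adjusted p from 1.8e-05 to 0.88 over the 12), among them the one without replicate 3 (0.019), fat body in 2 (0.033 to 0.44) and glia in 1 (0.032 to 0.88), each with its lowest value without replicate 2, Wnt, Hedgehog and BMP genes in 1 (2.7e-06 to 1), and cytosolic ribosomal proteins, as a list below other genes, in 1 (0.015 to 1). Circular shifts set a list against random positions, and protein-coding genes as a whole were bound 2.73 times as often as after shifts (9.06% against 3.32%), so that a list at the rate of all genes already lies above its shifted value. With that limit, 7 of the 21 lists passed in the permutation test, namely mitochondrial ribosomal proteins (adjusted p = 0.0088, against 0.20 to 1 in the exact test), heat shock and chaperones (0.048, against 0.16 to 0.77), autophagy (0.048, against 0.10 to 1), Wnt, Hedgehog and BMP genes (0.015), fat body (0.028), Hippo, JAK-STAT and growth control (0.048) and glia (0.049). The fat body list had 6 of 27 genes bound (exact test, adjusted p = 0.087), with Fer1HCH and Fer2LCH, the ferritin genes that share a locus, and Adh and bmm, and the glial list 4 of 15 (adjusted p = 0.11), namely moody, Gli, loco and pnt. The counts were 7 of 48 for Wnt, Hedgehog and BMP genes (sgg, shn, nkd and Apc the strongest), 6 of 42 for Hippo, JAK-STAT and growth control (Mnt, ft, dachs and Mer), 6 of 67 for imaginal disc patterning (bowl, Poxm, Dll and ft), and 0 of 12 for the homeotic complex. Of the neural lists, proneural and neuroblast genes had 2 of 31 (hb and grh) and differentiated neurons 5 of 52 (elav, sei, robo2 and Sh). Muscle had 3 of 39 (sls, Msp300 and Act87E), immune genes 6 of 53 (imd, GNBP1, cact and GNBP3), salivary gland secretions 0 of 27, and chorion and oogenesis 2 of 27, which were orb and Cp190, caught by its symbol. Among housekeeping lists, mitochondrial ribosomal proteins had 9 of 73 bound, and mRpS23, mRpL41 and mRpS10 lay at mean signal percentiles of 99.7, 99.6 and 99.6, with mRpL23 at 98.2. The locus of mRpS23 lies closer to CenG1A and that of mRpS10 closer to Art3, and the loci of grh, imd, GNBP1, orb, RpL34b, RpL32, RpL23, ND-MWFE, ND-42, Atg2, Atg17 and tRNA:Ala-AGC-2-2 also lie closer to another gene. Cytosolic ribosomal proteins had 5 of 93 (RpL34b, RpL32, RpL23 and RpS20), oxidative phosphorylation 5 of 95 (ND-ASHI, ND-MWFE, blw and ND-42), the proteasome 1 of 48 (Rpn3), and DNA replication and cell cycle 3 of 50 (Dp, RnrS and fzr). Heat shock and chaperones had 5 of 38, with Hsp27 at a percentile of 99.5 before Hsc70-5, Hsp26 and Hsp83. Autophagy had 4 of 30 (Atg2, Atg13, Atg17 and Atg18a), cell death 2 of 21 (hid and Diap1), and dosage compensation 1 of 7 (Sxl). In the exact test as first set, adjusted p for these lists, other than fat body and glia, was 0.298 or more.

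**Figure D2:**
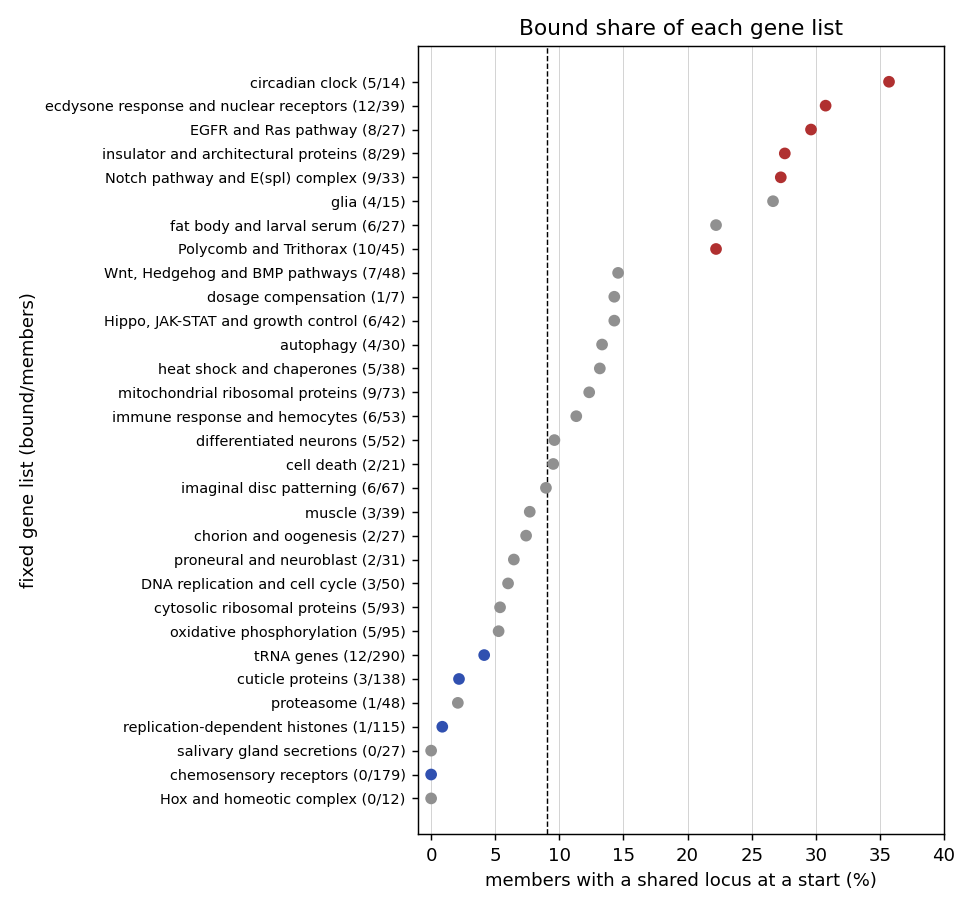
Share of the members of each gene list (%) with a shared locus within 500 bp of a transcript start, with bound and total members in brackets. Red points are lists above and blue points lists below their comparison genes at an adjusted p under 0.05, grey points are the others, and the dashed line is the share of all protein-coding genes, 9.06%.

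Several large genes held many shared loci along their bodies. kirre, a cell adhesion gene of muscle founder cells (X, 2740384 to 3134532), held 18 shared loci, sbb, which encodes a zinc finger protein (2R, 18278198 to 18357296), 17, the noncoding gene lncRNA:CR44357 on X 16, Snoo, the fly relative of the Ski and Sno corepressors (2L, 7891187 to 7984196), 15, and shn, a zinc finger factor of BMP signalling (2R, 11159086 to 11217394), 14. Per 10 kb of gene this came to 2.15 loci in sbb and 2.40 in shn, against 0.457 in kirre. Of the 5 genes, sbb and shn also had a shared locus at a start.

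**Figure D3:**
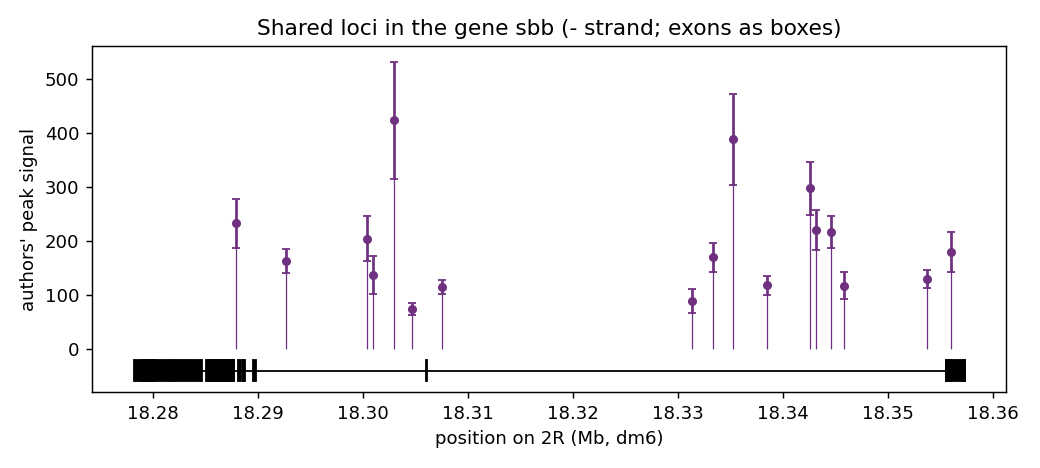
Shared loci along the gene sbb on 2R (position in Mb), with the mean signal of the 3 replicates in the authors' units as points, the SD as error bars, and exons as boxes under the axis line of the gene. The gene holds 17 shared loci.

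The tagged gene itself showed no thresholded peak within 2 kb in any of the 3 replicates. The ranked list of replicate 3 held 1 peak there, 54 bp past the end of CG8119, with a score of 182, below the threshold of 830, and the ranked lists of the other replicates held none. The nearest shared locus lay 7937 bp away.

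The sequence at the summits was rich in A and T. Windows of 100 bp either side of the locus centre had a GC content of 33.6% on average, against 42.8% in flanks 500 bp away, and 2987 of 3746 loci (79.7%) had the lower GC content at the summit. GC content averaged 29.0% within 10 bp of the centre and 45.9% at 180 to 200 bp. In the reported draw of the flank sides, the 20 leading 7-base words from 2L and 2R consisted of A and T alone, and all 20 were more frequent at summits on 3L, 3R and X, with odds ratios from 1.95 to 3.77 (exact McNemar test, adjusted p of at most 3.2e-22). TAATATA, for example, occurred in 15.6% of 2461 summit windows and 4.71% of flanks, and TTTAAAA in 25% and 9.51%. Words of A and T alone were found in 4 of 20 further draws, and the other 16 had a word with G or C among the 20, CAGTGCA in 15 draws, GAAAAAA in 4 and AGAAAAA in 2. The first draw made, which was replaced after its results had been seen, had 19 words of A and T alone and CAGTGCA.

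**Figure D4:**
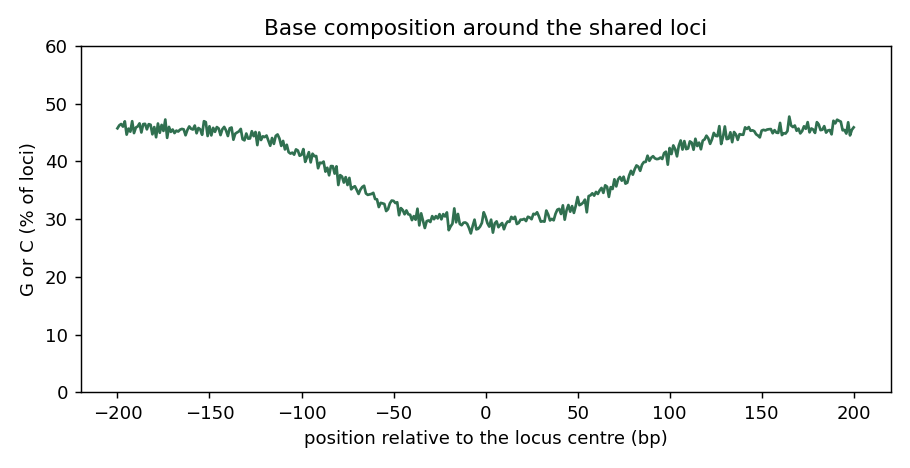
Percentage of the 3746 shared loci with G or C at each position, from 200 bp before to 200 bp after the locus centre. The average falls from 45.9% at 180 to 200 bp to 29.0% within 10 bp of the centre.

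Of the 30 fixed motif words, 4 were more frequent at summits than in flanks, 13 less frequent, and 13 did not pass. The number above was 6, 7 and 6 without replicates 1, 2 and 3, with 12, 10 and 10 below. It was 4 to 7 in 20 further draws of the flank sides, with 11 to 13 below, 5 in the first draw, with 11 below, and 9 with wider windows of 200 bp and farther flanks, with 3 below. Each changed set of loci also drew its flank sides anew. A word's call lost without a replicate therefore cannot be told apart from the effect of another draw. A run of 8 A bases was found in 24.0% of summit windows and 13.9% of flanks (exact McNemar test, adjusted p = 1.5e-28), the GATA word in 18.6% and 12.7% (adjusted p = 1.3e-11), the TATA box in 5.13% and 2.16% (adjusted p = 8.8e-11) and the homeodomain word TAATTA in 17.8% and 12.4% (adjusted p = 7.3e-10). In the first draw the TATA box was in 2.94% of flanks (exact test, adjusted p = 6.1e-06). At loci away from promoters its shares were 5.30% and 2.51% (exact test, adjusted p = 1.5e-06). In the same exact test the Pho word, at 14.3% and 22.1% (adjusted p = 1.3e-17), and the Adf-1-like triplet, at 2.22% and 5.74% (adjusted p = 3.0e-14), had the smallest p-values among the words below the flanks. With wider windows of 200 bp and farther flanks, changed together, the calls for the GATA word, TAATTA and the Adf-1-like triplet were lost (exact test, adjusted p = 0.96, 0.93 and 0.38, the highest of 9 alternatives for each). AGGTCA, the core of nuclear receptor sites, occurred in 3.47% of summit windows and 4.70% of flanks (exact test, adjusted p = 0.017), a call that held in 5 of 9 alternatives and was lost without replicate 1 (adjusted p = 0.095) and without replicate 3 (adjusted p = 0.36, the highest), and also in the first draw of the flank sides (exact test, adjusted p = 0.10). In the same exact test the palindromic element of the ecdysone receptor occurred in no summit window and 2 of 3746 flanks (adjusted p = 0.60). Against 1061 unbound promoter windows with the same offset and GC content, 4 words were more frequent and 3 less frequent at bound promoters. Of the 4 words above the flanks, whose GC content was not matched, only the run of A bases was also above these promoters. The others did not pass there, with the TATA box at 4.34% against 5.84% (Fisher's exact test, adjusted p = 0.28), TAATTA at 18.3% against 19.5% (adjusted p = 0.66) and the GATA word at 19.4% against 17.7% (adjusted p = 0.51). None of the 13 words below the flanks passed as lower at these promoters, with the Pho word at 13.5% against 17.2% (exact test, adjusted p = 0.056) and AGGTCA at 2.73% against 3.68% (adjusted p = 0.47), and GAGAG, its longer form and the Adf-1-like triplet passed as higher. GAGAG, the core of the GAGA factor site, occurred in 27.0% of bound and 16.4% of unbound promoters (Fisher's exact test, adjusted p = 9.7e-08). At summits of all loci it stood at 23.1% against 25.6% in flanks (exact McNemar test, adjusted p = 0.025), and that direction depended on the setting. With narrower windows of 50 bp GAGAG was also lower at summits, at 9.45% against 14.8% (exact test, adjusted p = 7.3e-12). The call was lost without replicate 2 (exact test, adjusted p = 0.17) and without replicate 3 (adjusted p = 0.95, the highest of 9 alternatives). With wider windows of 200 bp and farther flanks, changed together, GAGAG turned to 49.5% against 40.2% (exact test, adjusted p = 4.5e-15, the lowest). In the same Fisher's exact test its longer form was at 6.60% against 2.73% (adjusted p = 0.00023), the run of A bases at 22.6% against 15.1% (adjusted p = 0.00011) and the Adf-1-like triplet at 2.73% against 1.13% (adjusted p = 0.046). By the exact test the core promoter words Ohler 6, at 0.848% against 3.86% (adjusted p = 6.6e-05), and Motif 1, at 0.377% against 2.45% (adjusted p = 0.00032), and the BEAF word CGATA, at 23.9% against 29.6% (adjusted p = 0.019), were less frequent at bound promoters.

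The 4 thresholded lists of the whole series held 10370, 10603, 6603 and 7154 peaks, the first of them named conservative. They covered between 98.6% and 99.3% of the shared loci, and between 37.8% and 60.4% of their peaks held the centre of a shared locus. Per the deposited README texts, the lists were derived from the alignments of all 3 replicates. No replicate is named within a list, and which ones were paired for it is not given in the sources used here.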

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

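The ranked lists, the first and further flank draws, lists without genes caught by a prefix, and the arm test and rank agreement without each replicate were added after the data were seen. The promoter share and the X share of shared loci kept their direction and side of the threshold under every alternative run for them, with promoter shares from 19.5% (window 200 bp) to 44.6% (window 1000 bp). The word search gave 20 of 20 words past the threshold in every run, the highest count possible, though the words carried differed between draws. In the reported draw all 20 held A and T alone, so their passing restates the lower GC content of summits. Without each replicate in turn, words above the flanks numbered 6 to 7 against 4 reported, and flank sides were drawn anew for each changed set of loci. The rho of the remaining pair, over the loci that this pair shared, was 0.864 to 0.877. The rho from ranks over the whole lists was 0.825. The ranked lists at the same IDR gave 3817 shared loci, 20.2% of them on the X. Shared loci numbered 2125 in the stronger 50% of each list and 5665 when 2 of 3 replicates sufficed, and bound genes 929 and 2172, which follows from fewer or more loci entering. Bound genes numbered 774 with the window of 200 bp, which takes in fewer loci. The 6 lists above their comparison became 3 with summits joined within 50 bp and 3 with the window of 200 bp, and the cause was not tested. Under circular shifts, which set lists against random positions and not other genes, 13 lists lay above and 1 below. There the tRNA ratio was 1.53, which is no test against other genes. The Notch list turned to an odds ratio of 0.866 with the window of 200 bp, and the cause was not tested. Motif windows of 200 bp with farther flanks gave 9 words above and 3 below the flanks, and redrawn flank sides gave up to 7 above, and the cause was not tested. Among single words, GAGAG turned to an odds ratio of 1.47 and its longer form to 1.92 with windows of 200 bp and farther flanks, changed together (without replicate 3, 1.004 and 1.02, and the longer form 1.01 with 2 of 3 replicates), as did CAGCTG (1.07), the CA repeat (1.31), the CTCF word (1.03) and the Adf-1-like triplet (1.10), and the cause was not tested. For single lists, 109 odds ratios under alternatives kept their direction and side of the threshold, 22 no longer passed and 2 turned. The chemosensory and insulator lists kept their calls in all 12 alternatives of the exact test each, and under circular shifts. The histone and cuticle lists kept theirs without the genes caught by prefix (exact test, adjusted p = 0.00063 and 0.0035). No paired analysis was possible because there is 1 group. Unknown read depth limits every count of peaks.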

Other observations

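The tests of gene length and divergent genes, the tests of base composition and position of the word CAGTGCA, of transposable elements, of its direction, neighbouring bases and annotation class, and the test of replicate 3 were chosen after the results were seen. Bound protein-coding genes were longer than the rest, with a median of 4271 bp against 2049.5 bp (difference of mean log2 length 1.05, 1266 and 12702 genes, two-sided permutation p = 1e-05, the smallest that the permutations can give). A gene counts as bound through any of its annotated starts, and the number of starts per gene was not taken into account here. Genes in divergent pairs with starts within 1000 bp of each other were bound more often, 539 of 4480 (12%) against 727 of 9488 (7.66%) of other genes (odds ratio 1.65, Fisher's exact test, p = 2.2e-16). A locus between such starts counts for both genes, as at CenG1A and mRpS23.

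The AT-rich summits were examined against a pair of technical explanations, and no biological explanation was tested. Where both the summit and the flank window lay wholly in introns or intergenic DNA, the mean difference in GC content, summit minus flank, was still −8.73 percentage points (SE 0.223, 2045 loci), which argues against coding flanks as the whole cause. Of 79953 intronic and intergenic windows at least as AT-rich as the median summit window, 2.32% held a summit of any replicate. Only 10149 windows of any kind held a summit, which limits this share to 12.7% at most, so the value decides nothing about a general preference of the reads for AT-rich DNA. That preference, and binding in open chromatin shared with other proteins, stay open.

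The 7-base word CAGTGCA, which holds G and C, was noticed in the first draw of the flank sides, which was replaced by the reported one after its results had been seen, and it was among the 20 leading words in 15 of 20 further draws. In the reported draw it ranked 26 of 8192 words on 2L and 2R, and on 3L, 3R and X it occurred in 11.3% of summit windows against 4.10% of flanks (log2 odds 1.54, exact McNemar test, p = 2.7e-21). The 629 other words made of the same bases had a median log2 odds of −0.62, with 3 words above CAGTGCA (AGTGCAC, CACTGAG and GCACTGA). Shifted along CAGTGCA, on either strand, these 3 overlap most of it, so they are not independent of it. Of the matches of CAGTGCA, 0.612% stood at an annotated 3′ splice site. These values argue against composition and annotated splice sites. Of 436 shared loci with the word, 0% had their centre in an annotated transposable element. Only 5 of all shared loci did (0.133%), so a low share was fixed in advance. The test therefore cannot decide about repeat copies, and it looked at the centre of a locus and not at the match. Of the 490 matches of CAGTGCA, 85.3% (95% Wilson interval 81.9% to 88.2%, counting error only) lay over 40 bp from the centre, 15.6 percentage points more than for the words of the same bases. Of these, 343 read away from the centre and 75 toward it (exact binomial p = 5.0e-42), the 7 bases before the word were 77.3% C or T against 50.8% in flanks, and a candidate explanation, not tested, is an oriented element at the edges of an AT-rich site.

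The word occurred in 7.76% of promoter loci and 13.5% of other shared loci (Fisher's exact test, p = 1.9e-07), 12.3% of intronic and 17.4% of intergenic ones.

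Replicate 3 has the shortest list. Of the 1385 loci held by replicates 1 and 2 alone, 85.2% had a ranked peak of replicate 3 within 150 bp, against 6.27% after circular shifts and at most 8.81%. This is consistent with the same loci falling below the threshold in replicate 3, and depth, which is unknown, may be one reason.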
